A study of Rattus norvegicus with 12 samples.

How the data were processed

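RNA of the dorsomedial prefrontal cortex (dmPFC) was measured in rats that had received morphine or saline. Per the labels' protocols, tissue of 3 rats of one sex and one treatment was pooled at random before RNA was prepared, so each of the 12 libraries stands for 3 rats and each of the 4 groups for 9 rats in 3 libraries. The pools held separate rats, and the spread between libraries of a group is a spread between pools. Per the labels' protocols, RNA was purified on RNeasy columns, libraries were made with the TruSeq RNA v2 kit, which does not mark strand, and 50 bp paired-end reads were taken on a HiSeq instrument. Per the submitters' processing notes, FastQC, HISAT2 2.1.0 and edgeR were used with the rn6 build. The program that assigned reads to genes, its handling of reads with several matches and the annotation are not given in the sources used here.

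The authors deposited whole-number read counts per gene symbol, not normalized, for the 12 libraries. The values were whole, and the totals differed between libraries, from 17710556 in female saline 4 to 21058435 in male morphine 1. A count of 3, used as the floor for a gene with no reads, corresponds to between 0.142 and 0.169 CPM (counts scaled to the library total) in single libraries. Intervals from counts and this floor cover counting error only, since the reads carry no molecular identifiers. The table held 17336 symbols, of which 2660 had a count of 0 in each library. Of the symbols, 16945 matched a symbol or synonym in the RefSeq gene table of the GRCr8 assembly. That assembly differs from rn6, so it served only for names and for which genes are neighbours, and no coordinates, gene lengths or GC contents were used. Reads of overlapping genes on opposite strands cannot be told apart in these counts. Genes with near-identical copies, such as those of ribosomal proteins, and the alpha and gamma protocadherin clusters, whose members share exons, are uncertain to the extent that reads were split or left out.

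Gene counts were computed on as deposited with edgeR 4.0.16 in R 4.3.3. Genes with few counts were removed by filterByExpr, which left 12251 genes, library sizes were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with a robust prior was fitted with a mean for each of the 4 groups. From this fit 6 comparisons were tested with the quasi-likelihood F test. They were morphine against saline over both sexes (the mean of the female and the male difference), in females and in males, the sex difference of the morphine effect (interaction), female against male over both treatments, and female against male in saline. P-values were adjusted by Benjamini and Hochberg over the genes tested, and an adjusted p below 0.05 was called. Log2 fold changes are given with a standard error obtained from the F statistic. Adjusted p-values of single genes in the text come from this edgeR test unless another tool is named.

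Before the data were examined, the groups, tests, other settings to be tried, the rule for named genes and 34 gene lists with 1079 symbols were fixed. The lists covered cell types of cortex and neighbouring tissue, transmitter systems, and pathways chosen for opioid exposure and for tissue taken 24 h after the last of 10 daily injections. Of these symbols 1008 were present in the counts. Each list with at least 5 tested members, 32 in all, was tested against the other genes with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and, as an alternative, with an estimated correlation. The fry test, which asks whether the genes of a list move one way (directional) or change in either direction (mixed) without comparing them with other genes, was also run. Camera and fry p-values were adjusted over the 32 lists of a comparison.

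For each comparison the named genes were the 10 rising and the 10 falling genes with the largest log2 fold change among called genes with an average log2 CPM of at least 0 and no overlap between the libraries compared (within each sex for the comparison over both sexes, and with no such condition for the interaction). Where fewer than 5 genes passed in a direction, those genes and the 3 with the smallest p besides were named. Up to 4 members of each list with the smallest p, the opioid peptides and receptors, and the sex-linked genes were also named. Clustered protocadherins and genes with irregular counts were chosen after their values were seen.

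The procedure was tested on simulated counts made from the means, library sizes and dispersions of these libraries, with genes changed by known folds. Over both sexes it recovered 67.2% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 92.4% of those changed 3-fold among 12251 genes. For the sex difference it recovered 14.9%, 58.2% and 81.8%. In females it recovered 49.3%, 59.7% and 87.9%, and in males 41.8%, 74.6% and 93.9%. Camera with the preset correlation called 40 of 40 simulated lists of 30 genes shifted by 0.3 on the log2 scale and 2 of 40 unshifted lists. Simulated genes were drawn independently of each other, so these counts cannot tell how camera behaves for lists whose genes vary together. Libraries of a group differed by more than counting noise in the 12 pairs within groups (chi-square per gene of at least 6.69).

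Library features and the means of the gene lists were compared between treatments with two-sided exact permutation tests over the 400 assignments of treatment to libraries within each sex, whose smallest possible p is 0.005. The other settings were DESeq2 size factors, upper quartile scaling and library size alone within edgeR, no filter on low counts, a filter of 1 CPM in 6 libraries, a prior without robust estimation, DESeq2 1.42.0, limma voom with quality weights, 1 surrogate variable from sva 3.50.0, fits of only the 6 libraries compared, an additive model of sex and treatment, a replicate block where numbers are shared, a threshold of 0.1, and leaving out each library in turn. Leaving a library out leaves 2 in its group, and the other groups then share the estimate of spread. A covariate made of the ribosomal protein list and a fit without 3 libraries were added after the data were seen. A check of gene length or GC content was not run, because no annotation of the build used was at hand.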

Results

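The study asked how repeated morphine changes the transcriptome of the dorsomedial prefrontal cortex, a frontal region of the rat cortex. Morphine, an agonist of the mu opioid receptor, was injected under the skin at 5 mg/kg daily for 10 days, controls received saline, and tissue was taken 24 h after the last injection. There were 3 libraries each of female morphine, female saline, male morphine and male saline rats, each library a pool of 3 rats. Total counts ranged from 19425124 to 20516009 in female morphine, 17710556 to 19250504 in female saline, 19719006 to 21058435 in male morphine and 18178772 to 20153240 in male saline libraries. Treatment was the main axis of difference between libraries. The first principal component of log2 CPM held 36.5% of the variance, with means of −28.6 ± 13.1 and −16.3 ± 5.00 in female and male morphine libraries and 16.9 ± 9.86 and 28.0 ± 7.09 in female and male saline libraries (SD, n = 3 each; exact permutation p = 0.005, the smallest possible). The 50 most abundant genes took 13.4% ± 0.359 of counts in female morphine and 13.4% ± 0.00577 in male morphine libraries, against 14.3% ± 0.313 and 14.1% ± 0.254 in the saline libraries of females and males (SD, n = 3 each; exact permutation p = 0.005). Morphine libraries also held 1131030 more counts on average (exact permutation p = 0.03).

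In both sexes together, camera with the preset correlation called lists of ribosomal protein and respiratory chain genes lower in morphine libraries, and lists of transmitter receptor, G protein signalling and synaptic vesicle genes higher. With an estimated correlation none of these lists passed (adjusted p = 0.68 each). Efnb2, which encodes the membrane ligand ephrin-B2, rose 4.44-fold (log2 fold change 2.15 ± 0.19 SE, 6 against 6 libraries, adjusted p = 7.68e-06), from 1.94 ± 0.45 to 6.12 ± 1.49 CPM in females and from 0.809 ± 0.0793 to 5.12 ± 0.959 CPM in males (SD, n = 3 each). Rpl17, a protein of the large ribosomal subunit, fell by 1.12 ± 0.10 on the log2 scale (adjusted p = 1.26e-05), from 266.6 ± 15.2 to 102.9 ± 14.2 CPM in females and from 241.2 ± 31.3 to 132.2 ± 29.0 CPM in males (SD, n = 3 each). Of 12251 genes tested, 2327 rose and 1857 fell, which is 34.2% of them, with a median absolute log2 fold change of 0.43 among the called genes. More than 2-fold changes were found for 384 rising and 26 falling genes. The falling genes were more abundant, with a median log2 CPM of 5.97 against 4.42 for the rising genes.

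Genes were ranked among called genes with an average log2 CPM of at least 0 and no overlap of treatments within the sexes compared. By this ranking, the largest rises over both sexes included those of the protocadherins Pcdh11x (log2 fold change 2.31 ± 0.41) and Pcdhga12 (1.93 ± 0.27), the transmembrane protein gene Tmem255a (1.96 ± 0.30), Foxred2 (1.95 ± 0.39), the membrane-bound matrix metalloproteinase Mmp17 (1.85 ± 0.20), the deubiquitinase Usp5 (1.78 ± 0.31), Rtkn2 (1.76 ± 0.34), the uracil DNA glycosylase Smug1 (1.76 ± 0.31) and Gpr17 (1.74 ± 0.44), a receptor of the oligodendrocyte lineage. Their adjusted p-values lay between 1.97e-05 for Mmp17 and 0.0068 for Gpr17. Pcdh11x was expressed at a low level, 2.17 ± 0.696 CPM in female morphine and 0.416 ± 0.0939 CPM in female saline libraries (SD, n = 3). Among the largest falls in this ranking were 2 noncoding RNAs, Rmrp, the RNA of the RNase MRP complex (−1.57 ± 0.33), and Bc1, a brain cytoplasmic RNA (−1.25 ± 0.17). Npff, which encodes neuropeptide FF, fell by 1.40 ± 0.31 on the log2 scale (adjusted p = 0.00235), at 1.87 ± 0.732 CPM in female and 2.58 ± 0.874 CPM in male saline libraries (SD, n = 3). Rpl38 (−1.27 ± 0.28), Hsbp1l1 (−1.29 ± 0.34), LOC290595 (−1.11 ± 0.28), LOC310926 (−1.07 ± 0.14), LOC691921 (−1.05 ± 0.21) and Ccdc19 (−0.99 ± 0.27) completed the 10 largest falls in this ranking. The libraries of morphine and saline did not overlap in the same direction in both sexes for 2586 genes (21.1% of those tested), where chance gives 0.5%.

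Genes of translation and respiration moved down together. Whether the change of a gene followed its length was not checked, here or for the lists below. Of 78 tested cytosolic ribosomal protein genes, 71 fell and 0 rose (74 fell when adjusted over the list alone), with a median log2 fold change of −0.55 (camera adjusted p = 7.62e-23; adjusted p = 0.68 with an estimated correlation). Examples were Rps28 (−0.75 ± 0.09), Rps10 (−0.65 ± 0.08) and Rpl35a (−0.83 ± 0.11). Of 71 oxidative phosphorylation genes, 61 fell and 2 rose (62 and 2 adjusted over the list alone), with a median of −0.46 (camera adjusted p = 4.89e-21; adjusted p = 0.68 with an estimated correlation). The complex I subunits Ndufb7 (−0.79 ± 0.09) and Ndufb2 (−0.73 ± 0.08), the ATP synthase subunit Atp5i (−0.84 ± 0.09) and the cytochrome c oxidase subunit Cox7b (−0.67 ± 0.08) were among them. The mean of the ribosomal list per library ranged from −0.499 to −0.018 around its average in morphine libraries and from 0.132 to 0.547 in saline libraries, so the treatments did not overlap. Of 40 heat shock and chaperone genes, 6 rose and 9 fell (camera adjusted p = 0.169). The mitochondrial chaperone Hspa9 rose (0.86 ± 0.07), and the mitochondrial chaperonin Hspe1 (−0.58 ± 0.09) and the small heat shock protein gene Hspb1 (−0.69 ± 0.12) fell.

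In 6 lists of transmission and its signalling more genes rose than fell, and many did not pass. Of 39 cAMP and G protein signalling genes, 17 rose and 2 fell (17 and 3 adjusted over the list alone; camera adjusted p = 0.000512), including the phosphodiesterases Pde1a (1.30 ± 0.12), Pde1b (0.95 ± 0.08) and Pde4b (1.13 ± 0.12) and the G protein-gated potassium channel Kcnj9 (0.89 ± 0.08). Of 26 genes of metabotropic glutamate receptors and scaffolds, 13 rose and 0 fell (the same counts adjusted over the list alone; camera adjusted p = 0.000512), with Grm5 at 1.35 ± 0.20, Grm7 at 0.74 ± 0.10 and Dlg1 at 0.81 ± 0.08. Of 42 synaptic vesicle and release genes, 20 rose and 2 fell (22 and 2 adjusted over the list alone; camera adjusted p = 0.00126), with Napb at 1.70 ± 0.17 and Syt11 at 1.11 ± 0.11. Of 26 monoamine and acetylcholine receptor genes, 9 rose and 0 fell (the same adjusted over the list alone; camera adjusted p = 0.003), among them the serotonin receptor Htr2a (1.63 ± 0.24), the nicotinic subunit Chrnb2 (1.48 ± 0.16) and the beta-1 adrenergic receptor Adrb1 (0.96 ± 0.14). Of 19 GABA receptor and transporter genes, 10 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.00374), with the receptor subunits Gabra4 at 1.32 ± 0.14 and Gabra3 at 1.06 ± 0.10 and the transporter Slc6a11 at 1.28 ± 0.19. Of 26 ionotropic glutamate receptor genes, 11 rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.0455), with Grid1 at 1.45 ± 0.22, Grin3a at 1.25 ± 0.25 and Gria1 at 0.67 ± 0.12. None of the lists passed with an estimated correlation, where each of these 6 had an adjusted p = 0.68.

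Of the opioid peptides and receptors, 3 of 6 tested genes passed over both sexes (the same 3 adjusted over the list alone), and the list as a whole did not (camera adjusted p = 0.518). Penk, the precursor of the enkephalins, fell by 0.41 ± 0.12 on the log2 scale (adjusted p = 0.0206), from 207.1 ± 30.6 to 158.3 ± 18.6 CPM in females and from 208.7 ± 49.9 to 153.7 ± 29.1 CPM in males (SD, n = 3 each). Pnoc, the precursor of nociceptin, fell by 0.37 ± 0.10 (adjusted p = 0.00781), and its receptor gene Oprl1 rose by 0.31 ± 0.09 (adjusted p = 0.0124). Pomc (−0.42 ± 0.19, adjusted p = 0.103), Pdyn (0.37 ± 0.19, adjusted p = 0.155) and the delta receptor gene Oprd1 (−0.14 ± 0.43, adjusted p = 0.837) did not pass. The mu receptor gene Oprm1 had 19 counts and the kappa receptor gene Oprk1 16 counts over the 12 libraries, too few to be tested. Among 29 stress neuropeptides and receptors 3 rose and 7 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.414), with the tachykinin receptor Tacr3 up by 1.33 ± 0.14, its ligand gene Tac3 at −0.64 ± 0.09 and Cck at −0.65 ± 0.10.

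Lists of activity, hormone and other responses were mixed over both sexes. Over all 12251 tested genes 2327 rose and 1857 fell, which is the background for the counts in these lists and in the cell type markers. Of 34 immediate early genes 7 rose and 1 fell (camera adjusted p = 0.51), with the transcription factors Egr1 (0.88 ± 0.15) and Nr4a3 (0.96 ± 0.21) and the pseudokinase Trib1 (1.51 ± 0.32) up and Gadd45g down (−0.54 ± 0.10). Of 25 glucocorticoid responsive genes 6 rose and 2 fell (camera adjusted p = 0.603), with Fkbp5 (0.36 ± 0.07) and the glucocorticoid receptor gene Nr3c1 (0.26 ± 0.05) up and the metallothionein Mt1a down (−0.89 ± 0.14). Of 16 circadian clock genes 5 rose (camera adjusted p = 0.109), including Per1 (0.47 ± 0.13) and Tef (0.32 ± 0.06). Of 30 cholesterol synthesis genes 8 rose and 3 fell (camera adjusted p = 0.303). Of 34 neurotrophin and growth factor genes 7 rose and 3 fell (camera adjusted p = 0.518), with the receptor Fgfr1 at 0.57 ± 0.09. Of 33 perineuronal net and extracellular matrix genes 8 rose and 1 fell (camera adjusted p = 0.169), with the lecticans Bcan (0.47 ± 0.07) and Ncan (0.64 ± 0.11) up. Of 32 inflammatory signalling genes 2 rose, Ptgs2 (1.02 ± 0.20) and Il1r1 (1.13 ± 0.30), and 0 fell (camera adjusted p = 0.857). Of 38 interferon response genes 1 rose, Stat2 (0.40 ± 0.09), and 9 fell (the same adjusted over the list alone; camera adjusted p = 0.0466; adjusted p = 0.68 with an estimated correlation), among them B2m (−0.48 ± 0.08), Bst2 (−0.92 ± 0.16) and Ifitm3 (−0.60 ± 0.14), while in males alone 0 fell.

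Among markers of cell types, camera with the preset correlation called 2 vascular lists lower over both sexes, and most of their members did not pass. In males alone neither was called (camera adjusted p = 0.0576 for mural and 0.139 for endothelial markers). Of 34 markers of mural cells, fibroblasts and meninges 9 fell and 0 rose (8 fell adjusted over the list alone; camera adjusted p = 0.00275; adjusted p = 0.68 with an estimated correlation), with Tagln at −0.65 ± 0.09 and Mgp at −0.61 ± 0.11. Of 30 endothelial markers 8 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 0.00701; adjusted p = 0.68 with an estimated correlation), with Ramp2 at −0.42 ± 0.06, Egfl7 at −0.66 ± 0.10 and the transporter Slc16a1 at 0.46 ± 0.09. Of 18 excitatory neuron markers 9 rose and 2 fell (camera adjusted p = 0.086), including Tbr1 (1.27 ± 0.14) and the vesicular glutamate transporter Slc17a7 (0.74 ± 0.09). Of 24 deep layer markers 7 rose and 2 fell (camera adjusted p = 0.414). Of 18 upper layer markers 4 rose (camera adjusted p = 0.324). Of 26 striatal neuron markers 3 rose and 3 fell (camera adjusted p = 0.466). Of 27 inhibitory neuron markers 2 rose and 6 fell (camera adjusted p = 0.603), with parvalbumin (Pvalb, −0.59 ± 0.08), somatostatin (Sst, −0.74 ± 0.14) and Vip (−0.39 ± 0.09) down. Of 30 astrocyte markers 3 rose and 4 fell (camera adjusted p = 0.518). Of 30 microglia markers 4 rose, with Cx3cr1 at 0.79 ± 0.12, and 4 fell, with Aif1 at −0.74 ± 0.10 (camera adjusted p = 0.859). Of 28 oligodendrocyte and myelin markers 1 rose and 5 fell, with Mbp at −0.57 ± 0.12 (camera adjusted p = 0.788). Of 11 oligodendrocyte progenitor markers 3 rose and 1 fell (camera adjusted p = 0.295). Of 13 choroid plexus and ependyma markers 1 rose and 1 fell (camera adjusted p = 0.518). Of 8 blood cell markers 1 rose and 1 fell (camera adjusted p = 0.311). The median of the astrocyte (−0.01), microglia (−0.03), inhibitory neuron (0.01) and inflammatory (0.00) lists changed sign with the scaling of the libraries, and the camera direction of the oligodendrocyte list was down at a median of 0.04.

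**Figure D1:**
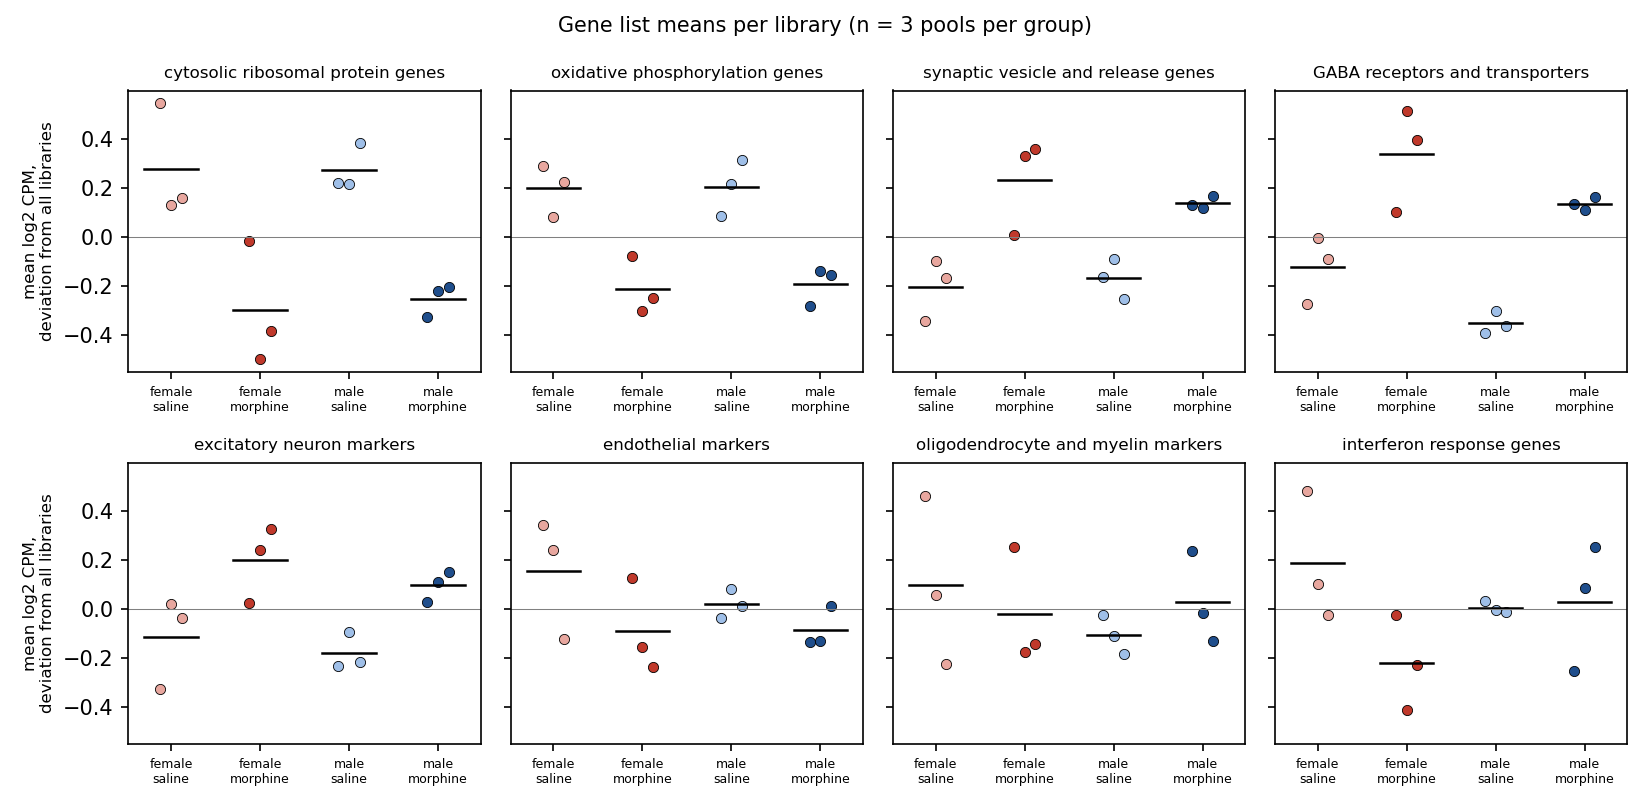
For the lists drawn, each point is the mean log2 CPM of the list's tested genes in one library, as a deviation from the mean over the 12 libraries, with a line at the mean of each group (n = 3). The ribosomal protein list lies between −0.499 and −0.018 in morphine libraries and between 0.132 and 0.547 in saline libraries.

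In the lists tested over both sexes, counts adjusted over the list alone differed from those over all genes by at most 3 members in any list. The directional fry test called 14 of the 32 lists and the mixed test 29. The means of the lists per library were compared between treatments over both sexes by exact permutation, with p adjusted over the 34 lists. Of the lists called by camera, the ribosomal, oxidative phosphorylation, cAMP and G protein, metabotropic glutamate, synaptic vesicle and GABA lists (adjusted p = 0.0189 each) and the monoamine and ionotropic glutamate lists (0.0243 each) passed. The mural (0.17), endothelial (0.17) and interferon (0.262) lists did not. Of the lists that camera did not call, the means of excitatory neuron, striatal neuron and perineuronal net (0.0189 each), deep layer, clock and cholesterol (0.0243 each) and upper layer (0.0425) genes were higher with morphine. So was the mean of the X-linked list (0.034), whose 3 tested genes were too few for camera. The excitatory neuron mean was higher by 0.297, beside 0.372 for synaptic vesicle and 0.297 for ionotropic glutamate genes. Scaling by library size alone gave 3093 rising and 1307 falling genes, 70.3% rising against 55.6%, and moved the median log2 fold change of all genes from 0.013 to 0.081. With the mean of the ribosomal list as a covariate, chosen after the data were seen, the edgeR test called 0 genes. That mean did not overlap between treatments, so the covariate fits here and within each sex cannot tell it apart from treatment.

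In females, the largest rises in the same ranking included Pcdh11x (log2 fold change 2.36 ± 0.58), Foxred2 (2.23 ± 0.56), the calcium/calmodulin kinase subunit Camk2g (2.14 ± 0.44), the phosphatase-like gene Mtmr12 (1.91 ± 0.35) and Amigo1 (1.91 ± 0.25), a neuronal adhesion protein. Each had 3 morphine libraries above the 3 saline libraries, and the largest adjusted p was 0.0118, for Foxred2. Pcdhga12 (2.15 ± 0.39), Tmem255a (2.1 ± 0.42), Pcdhga8 (2.02 ± 0.42), Fut10 (2.0 ± 0.59) and Rtkn2 (1.88 ± 0.47) rose as well. Among the falls were Rmrp (−2.05 ± 0.48), Fam50a (−1.60 ± 0.28), Rpl38 (−1.60 ± 0.39), the schlafen Slfn3 (−1.45 ± 0.41), Npff (−1.48 ± 0.45) and the interferon-induced genes Isg15 (−1.50 ± 0.37) and Bst2 (−1.27 ± 0.23). Isg15 was at 11.8 ± 6.57 CPM in female saline and 4.18 ± 1.83 CPM in female morphine libraries (SD, n = 3). Rpl17 fell by 1.37 ± 0.15, and LOC290595 (−1.35 ± 0.40) and Mei4 (−1.28 ± 0.40) fell too.

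In females 1411 genes rose and 1026 fell, and 34.3% of tested genes had no overlap between treatments where chance gives 10%. Ribosomal protein genes fell in 62 of 78 cases (70 adjusted over the list alone; camera adjusted p = 2.12e-24) and oxidative phosphorylation genes in 55 of 71 (62 adjusted over the list alone; camera adjusted p = 8.32e-23). Synaptic vesicle genes rose in 17 of 42 cases (17 adjusted over the list alone; camera adjusted p = 0.000203), metabotropic glutamate genes in 12 of 26 (12 adjusted over the list alone; camera adjusted p = 0.000182) and cAMP and G protein genes in 15 of 39 (18 adjusted over the list alone; camera adjusted p = 0.000411). Of 38 interferon response genes 7 fell and 0 rose (10 fell adjusted over the list alone; camera adjusted p = 0.000182), including B2m (−0.64 ± 0.11), Ifitm3 (−0.90 ± 0.21) and Rtp4 (−1.25 ± 0.29). Female saline 4 stood apart in the mean of this list (0.481, against 0.101 and −0.023 in the other female saline libraries), and without it the camera adjusted p was 0.00425. Of 16 clock genes 3 rose (camera adjusted p = 0.0272), with Per1 at 0.74 ± 0.18. Endothelial (1 rose, 6 fell), mural (3 fell) and heat shock (3 rose, 7 fell) lists also passed camera downward, and GABA (9 rose), monoamine and acetylcholine (7 rose) and ionotropic glutamate (7 rose) lists upward. None of the 13 lists passed with an estimated correlation (smallest adjusted p = 0.41 with an estimated correlation). Of the opioid genes Oprl1 rose (0.41 ± 0.13, adjusted p = 0.0314), and Penk did not pass (−0.39 ± 0.18, adjusted p = 0.146). Without female morphine 2 the count of called genes was 1039 and without female morphine 3 it was 1371, against 2437 with them. Scaling by library size alone gave 70.6% rising against 57.9%, and the ribosomal covariate left 0 called genes in females.

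In males, Efnb2 rose most among the named genes (log2 fold change 2.65 ± 0.29, adjusted p = 0.000302), followed by Pcdh11x (2.27 ± 0.59), Xk (2.25 ± 0.54), the inward rectifier potassium channel Kcnj2 (2.21 ± 0.56) and the protocadherins Pcdhga2 (2.08 ± 0.31) and Pcdhga7 (1.94 ± 0.33). Mmp17 (1.89 ± 0.29), Usp5 (1.89 ± 0.44), the muscarinic receptor Chrm2 (1.87 ± 0.54) and the histamine receptor Hrh1 (1.86 ± 0.43) rose as well. Among the falls were the T-box factor Tbx19 (−1.89 ± 0.50), Tnmd (−1.59 ± 0.52), Hsbp1l1 (−1.38 ± 0.46), Bc1 (−1.36 ± 0.23), the latent TGF-beta binding protein Ltbp2 (−1.36 ± 0.37), RGD1310262 (−1.35 ± 0.34) and Npff (−1.33 ± 0.42). LOC691921 (−1.30 ± 0.30), Clic2 (−1.18 ± 0.37) and Ttc25 (−1.18 ± 0.34) fell too. Hspa9 rose by 1.08 ± 0.10, from 57.5 ± 1.19 to 121.4 ± 5.22 CPM (SD, n = 3 each; adjusted p = 0.000118).

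In males 1266 genes rose and 961 fell, and 38.9% of tested genes had no overlap between treatments where chance gives 10%. Ribosomal protein genes fell in 41 of 78 cases (64 adjusted over the list alone; camera adjusted p = 1.67e-18) and oxidative phosphorylation genes in 50 of 71 (56 adjusted over the list alone; camera adjusted p = 1.67e-18). The cAMP and G protein list rose in 15 of 39 genes (16 adjusted over the list alone; camera adjusted p = 0.000784), the monoamine and acetylcholine list in 9 of 26 (9 adjusted over the list alone; camera adjusted p = 0.00269), the metabotropic glutamate list in 10 of 26 (11 adjusted over the list alone; camera adjusted p = 0.00269), and the GABA list in 7 of 19 (8 adjusted over the list alone; camera adjusted p = 0.00376). The synaptic vesicle list rose in 13 of 42 genes (13 adjusted over the list alone; camera adjusted p = 0.00948). None of these 7 lists passed with an estimated correlation (smallest adjusted p = 0.776 with an estimated correlation). Of 38 interferon response genes 1 rose, Stat2 (0.47 ± 0.13), and 0 fell (camera adjusted p = 0.947). None of the 6 opioid genes passed in males under edgeR, with Penk at −0.44 ± 0.18 (adjusted p = 0.104) and Pnoc at −0.34 ± 0.14 (adjusted p = 0.0988). Inhibitory neuron markers fell in 6 of 27 genes, with Cort at −1.10 ± 0.25 and Tac1 at −1.0 ± 0.26 (camera adjusted p = 0.416). Without male saline 6 the count of called genes was 1146 against 2227 with it. With the ribosomal covariate 4 genes were called, of which 3 were among the 2227. Scaling by library size alone gave 70.9% rising against 56.8%.

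The morphine effects of the sexes were compared across genes. Females and males shared 903 rising genes, where independent lists would share 145.8, and 639 falling genes, where 80.5 would be shared, and 0 genes were called in opposite directions. The genes called alike in both sexes included Pcdh11x and Tbr1 on the rising side and Rpl17, Npff and Pvalb on the falling side. Over the 12251 genes the log2 fold changes of the sexes had a Pearson correlation of 0.653 and a Spearman correlation of 0.699, and 77.3% had the same sign. These are correlations across genes, which are not independent replicates, and the sexes shared no libraries. Without male morphine 1 the Pearson correlation was 0.534, and without male saline 6 it was 0.542.

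**Figure D2:**
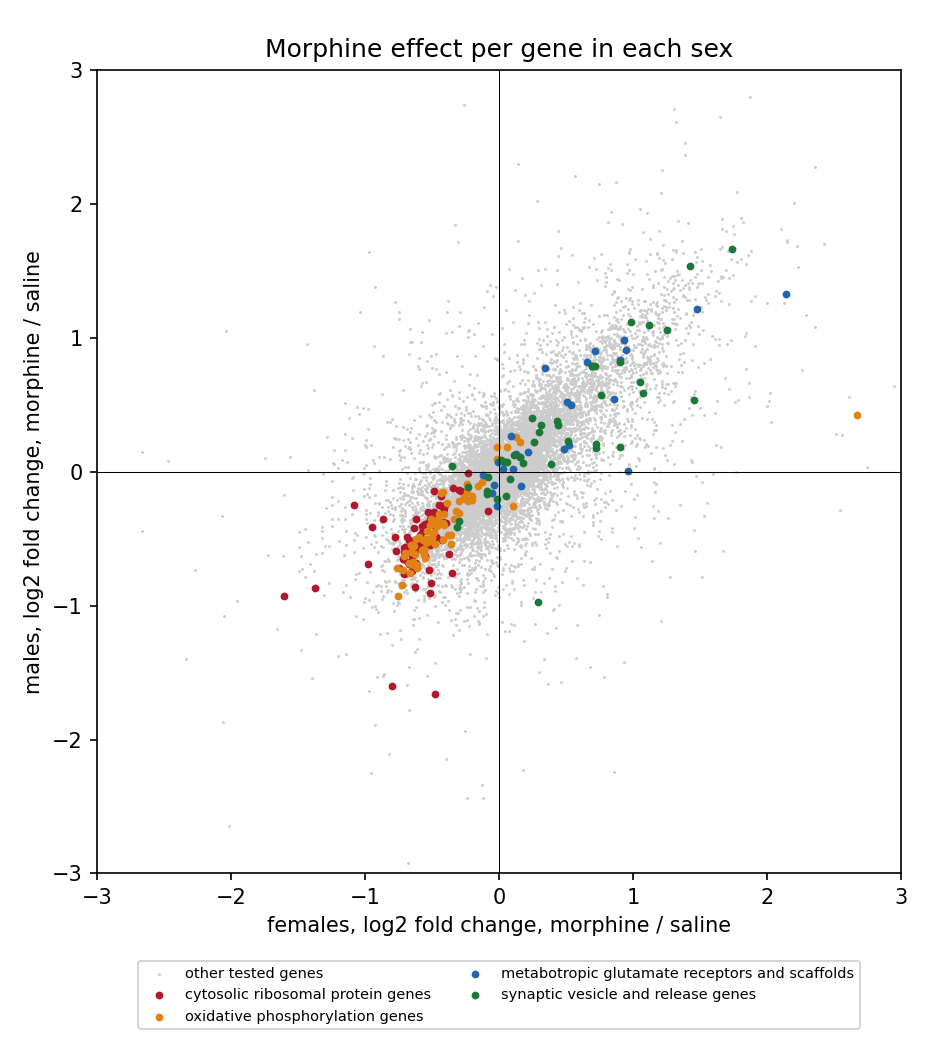
Each point is one gene, with its log2 fold change of morphine against saline in females on the x axis and in males on the y axis (3 libraries per group), and 4 lists are drawn in colour. Of 12251 tested genes 12237 lie within the axes, and the correlation across the tested genes is 0.653. Ribosomal and oxidative phosphorylation genes lie mostly at lower left.

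Whether morphine acted differently in females and males was tested with the interaction. No gene passed in the edgeR test, with 395 of 12251 genes at an unadjusted p below 0.05. DESeq2 and limma voom also called 0 (416 and 887 genes at an unadjusted p below 0.05). The edgeR and DESeq2 numbers are below the share of 0.05 that chance gives, and that of limma voom is above it. The genes with the smallest p were, with a stronger rise in females, Rsph10b (difference of log2 fold changes 1.25 ± 0.32), Sh3pxd2a (1.32 ± 0.34) and Caln1 (1.63 ± 0.43), and in the other direction Ddah1 (−0.71 ± 0.16), Fam50a (−1.43 ± 0.39) and Gem (−0.92 ± 0.26). None of these 6 passed, with an adjusted p = 0.999 each. Fam50a was called in females and not in males, and its interaction (unadjusted p = 0.00212) did not pass. This does not show that the sexes agree, since simulated 2-fold differences between the sexes were recovered in 58.2% of cases. Camera with the preset correlation called 7 lists, each more negative in females, led by the interferon response list (median difference −0.38; camera adjusted p = 2.48e-09; adjusted p = 0.617 with an estimated correlation). Female saline 4, which held the highest means of the microglia (0.363), choroid plexus (1.151), endothelial (0.344) and oligodendrocyte (0.462) lists among the 12 libraries, also held the highest interferon mean (0.481). None of the 7 lists passed with an estimated correlation. The count of called lists was 2 without female saline 4, where the ribosomal list turned upward (adjusted p = 0.815), and 12 without female morphine 1.

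Females and males were compared over both treatments, which also checks the sex labels. Eif2s3y, a Y-linked subunit of a translation initiation factor, had 2052 to 2409 counts in male and 0 to 2 counts in female libraries, a ratio of 3270 (95% interval 1270 to 12000, counting error only). The symbol Ddx3, which GRCr8 lists as a synonym of the Y-linked helicase Ddx3y, had 273 to 779 counts in male and 0 to 3 counts in female libraries, a ratio of 981 (335 to 4760). A separate symbol Ddx3y had 2 to 8 counts in female and 0 to 9 counts in male libraries, so the symbols were not treated as one gene. LOC680227 had 46 to 125 counts in female and 0 to 2 in male libraries, a ratio of 127 (49.1 to 467). These counts separated the sexes in the 12 libraries as labelled. Of the other genes, the X-linked Eif2s3x was higher in females (log2 fold change 0.73 ± 0.06, adjusted p = 2.45e-06) at 227.4 ± 14.9 CPM against 137.2 ± 8.61 CPM (SD, n = 6 each), and Dkc1, a pseudouridine synthase, was lower in females (−0.50 ± 0.07, adjusted p = 0.0127).

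These 5 genes, Eif2s3x, LOC680227, Dkc1, Ddx3 and Eif2s3y, were those called between the sexes by edgeR, with 1463 genes at an unadjusted p below 0.05. Hspa9 (0.35 ± 0.07), Apln (0.33 ± 0.07) and Tmem30a (0.45 ± 0.10) with higher values in females, and B4galnt4 (−0.31 ± 0.05), Cep131 (−0.36 ± 0.06) and MAST1 (−0.31 ± 0.06), with lower, had the next smallest p and did not pass (adjusted p of 0.0599 or more). In saline alone 5 genes were called, with Cep131 (−0.56, adjusted p = 0.0344) in place of Dkc1. The count depended on the tool and on the settings. DESeq2 called 125 genes over both treatments and 132 in saline, and limma voom 223 and 20, and edgeR with 1 surrogate variable 192 and 308. Without female morphine 1 the count over both treatments was 48 and in saline 8. In the list of X-linked genes outside inactivation, Ddx3x rose with morphine over both sexes (0.39 ± 0.10), and 2 of 3 tested genes did not pass. In the Y-linked list Eif2s3y passed with morphine over both sexes (−1.94 ± 0.63, adjusted p = 0.0309), a call that rests on 0 to 2 counts in female libraries, and Ddx3 passed in males (0.82 ± 0.20, adjusted p = 0.0127).

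**Figure D3:**
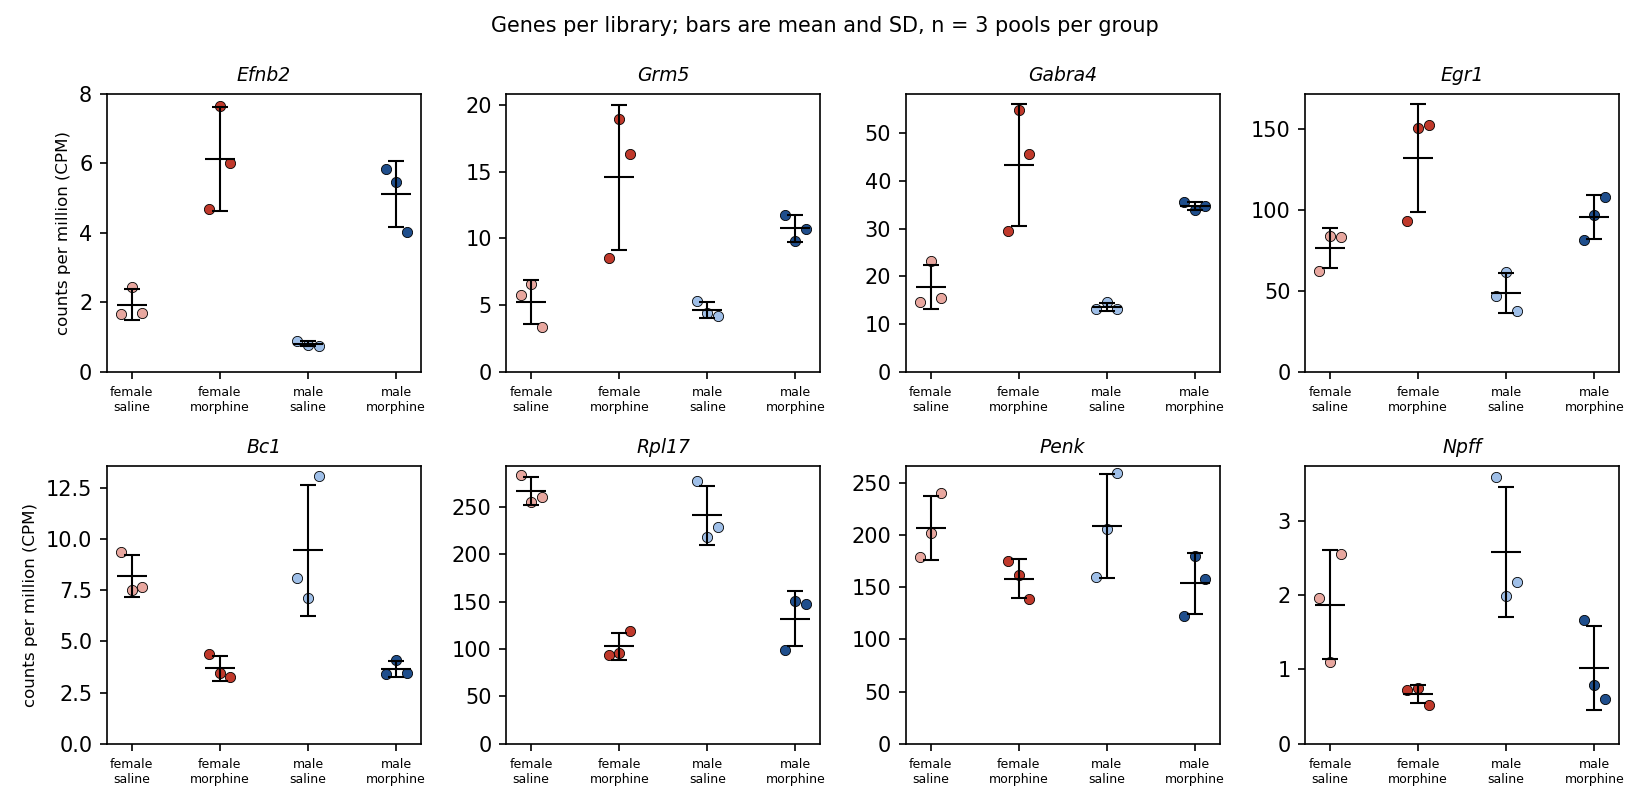
Each point is the CPM of the named gene in one library, by group, with bars for the mean and SD of each group (n = 3). Efnb2 lies higher in each morphine library than in each saline library of the same sex.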

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

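The interferon list was chosen for weighing after its camera result was seen, and what its tests should show was written down before they were run. A difference between the sexes in the morphine effect, tested with the interaction, brought 7 gene lists here, each more negative in females under camera with the preset correlation. They were interferon response genes (median difference of log2 fold changes −0.38, adjusted p = 2.48e-09), oligodendrocyte and myelin markers (−0.28, adjusted p = 9.99e-05), microglia markers (−0.18, adjusted p = 0.0031), endothelial markers (−0.14, adjusted p = 0.0113), cytosolic ribosomal protein genes (−0.10, adjusted p = 0.0153), heat shock and chaperone genes (−0.08, adjusted p = 0.0153) and choroid plexus and ependyma markers (−0.59, adjusted p = 0.0287). With an estimated correlation the adjusted p was 0.617 for the interferon list and 0.924 for the other 6, so these calls rest on the preset correlation. Directional fry, which asks another question, gave 0.957 for each. No single gene passed the interaction in edgeR (395 at an unadjusted p below 0.05), DESeq2 or limma voom.

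In the interferon list, 35 of 38 members were more negative in females and 3 had an unadjusted p below 0.05. One library, female saline 4, held the highest mean of this list, and without it the adjusted p was 0.00011 (between 2.14e-11 and 0.617 over the other camera fits), so that library alone does not account for the preset-correlation call. The mean difference over the members went from −0.43 to −0.28 without it, so that library carries part of its size. A larger share of microglia, endothelial or choroid plexus cells in that library was tested by adding the means of these 3 lists as covariates, none of whose members is in the interferon list, and the adjusted p was 0.000121, with the median moving from −0.39 to −0.27. Without female saline 4 the heat shock list kept an adjusted p of 0.00181 and the oligodendrocyte (0.331), microglia (0.473), endothelial (0.478), choroid plexus (0.546) and ribosomal (0.815, now in the other direction) lists did not pass. Fits without another single library also ended the camera call for the heat shock (0.173 without male saline 4), ribosomal (0.923 without female morphine 2), endothelial (0.409 without female morphine 3), choroid plexus (0.295 without male saline 5) and microglia (0.154 without female morphine 3) lists. A sex difference of the interferon response to morphine, which the design names, and correlated variation of these genes between pools, as the value of 0.617 with an estimated correlation leaves possible, both stay open.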

How the results depend on the processing

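The ribosomal covariate and the fit without 3 libraries (female morphine 1, female saline 4 and female saline 5) were chosen after the data were seen, and both were run for the 6 comparisons. The count of called genes over both sexes was 4184, with 3335 without female morphine 2 and 4530 without female morphine 1. In females it was 2437 and ranged from 1039 without female morphine 2 (1371 without female morphine 3) to 2918 without female morphine 1. In males it was 2227 and ranged from 1146 without male saline 6 to 2479 without female morphine 1. The interaction count was 0 in each of the 12 fits without 1 library, and also 0 in edgeR under each other setting, in DESeq2 (416 at an unadjusted p below 0.05) and in limma voom (887). Fits of only the 6 libraries compared gave 1722 in females and 2613 in males. The other scalings, filters and tools, the surrogate variable and the additive model left the counts over both sexes between 4027 and 4900, and without the 3 libraries they were 4088, 2074 in females and 2878 in males.

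With the ribosomal covariate the count was 0 over both sexes, 0 in females, 4 in males, 21 for female against male and 16 for it in saline. Over both sexes the standard error of the called genes went from a median of 0.09 to 0.17 and their change in the called direction from 0.43 to 0.21. The covariate did not overlap between treatments (morphine −0.499 to −0.018, saline 0.132 to 0.547), so it takes up part of the treatment difference. The lost calls and changed signs therefore cannot tell it apart from treatment. Under this covariate 17 named results changed sign. Rmrp was 0.066, Rpl38 0.15, Ddx3x −0.12, Bhlhe40 −0.26, Nr4a3 −0.12, Trib1 −0.017, Ptgs2 −0.16, Fcer1g 0.15, Pdgfa 0.031, Ppp1r14a 0.033, Mbp 0.008, Cd9 0.23, Bcas1 0.10, Wfs1 −0.034, Rasgrf2 −0.32 and Cux2 −0.017 over both sexes, and Isg15 was 0.045 in females. Ddx3 did not pass over both sexes (log2 fold change −1.22, adjusted p = 0.21), and its sign turned in the additive model of sex and treatment (0.765) and without female saline 4 (0.41). The ribosomal list in the interaction turned upward without female saline 4 (adjusted p = 0.815), and its adjusted p ranged from 2.01e-12 without female morphine 1 to 0.923 without female morphine 2. Beyond the covariate's separation of the treatments, the cause of these changes was not tested.

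For female against male, 5 genes were called, and 4 to 48 without 1 library (48 without female morphine 1). DESeq2 called 125, limma voom 223, the fit with 1 surrogate variable 192, the fit without the 3 libraries 25 and a threshold of 0.1 gave 10. In saline alone 5 were called, and 4 to 8 without 1 library (8 without female morphine 1). There DESeq2 called 132, limma voom 20, the surrogate variable fit 308, the fit of the 6 libraries compared 8 and a threshold of 0.1 gave 12. The cause was not tested. The correlation of the sexes' effects, 0.653, was 0.836 over genes with an average log2 CPM of at least 3 and ranged from 0.534 without male morphine 1 (0.542 without male saline 6) to 0.629 without female morphine 1.

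Of the gene lists, camera called 11 over both sexes (9 to 12 without 1 library), 13 in females (11 to 17), 7 in males (7 to 10) and 7 in the interaction. The interaction count was 12 without female morphine 1, 4 without female morphine 2, 3 without female morphine 3, 2 without female saline 4 and 4 without male morphine 3. With an estimated correlation each of these counts was 0. Mixed fry called 29 lists over both sexes, 23 in females, 21 in males and 0 in the interaction, and directional fry 4 in males and 0 in the interaction. These tests ask other questions of a list.

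Same-numbered female and male libraries of one treatment were checked for pairing. Their deviations from the group means had correlations from −0.041 to 0.213, with 3 of 6 above 0.1. Pairing was to be accepted only with each of the 6 above 0.1, so the libraries were treated as unpaired. Hints of pairing remain, since 9 of 12 libraries correlated best with their own number and numbers 1 and 4 lay high on the second principal component in both sexes (14.9 to 23.1, the others at −2.04 or lower). With the replicate block the interaction count was 0, female against male 95 and in saline 152. The surrogate variable also set numbers 1 and 4 of both sexes apart (−0.626 in female saline 4 to −0.227 in male saline 4, the others at −0.00558 or higher). Pairing by number was not possible over both sexes, in females and in males, because morphine and saline libraries share no numbers. A block by order within the groups was not tried. Of 205 named results, 199 kept their side of the threshold with DESeq2, 193 with limma voom and 199 with library size alone. Depth limits the text at low counts, as for Oprm1 (19 counts in all) and Oprk1 (16 counts), where a change was not detectable.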

Other observations

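The clustered protocadherins and the genes with irregular counts were chosen after their values were seen, as were the comparison of variation within groups, the ribosomal covariate and the test of counting noise. Clustered protocadherins are adhesion proteins encoded in 3 gene arrays and expressed in differing sets by single neurons, and no enrichment was tested for them. Of 37 tested members 24 rose and 0 fell over both sexes, with a median log2 fold change of 1.29, and the median was 1.27 to 1.36 under the other scalings. In females 11 rose (median 1.11) and in males 12 (median 1.26), with 0 falling in either sex under edgeR and 0 differing between the sexes. Pcdhga12 (1.93 ± 0.27) was among them. Members of the alpha array share exons, as do those of the gamma array, so their counts are not independent of each other.

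About 34.2% of the tested genes differed between morphine and saline, and the tables were searched for a technical source. A property of the RNA or the library that varies whatever the treatment may add to it. The genes called in the other sex, rising minus falling, varied within groups with an SD of 0.241 in females and 0.15 in males. This was 6.92 and 3.26 times the upper bound of random sets matched on expression, so an axis of shared variation exists without a treatment difference. Genes that vary together between pools for any reason would exceed that bound, so it does not point to a library property. Between treatments, rising minus falling ranged from −1.57 to −1 in female morphine and −2.46 to −2.05 in female saline libraries. In males it ranged from −1.85 to −1.53 and −2.98 to −2.65 in the same order, so the treatments did not overlap within either sex. Whether that axis is the whole difference cannot be told apart from treatment. With the ribosomal mean as a covariate 0 called genes kept their call, their median change in the called direction fell from 0.43 to 0.21 while its standard error rose from 0.09 to 0.17, and 85.2% kept their sign, but the covariate did not overlap between treatments (saline 0.132 to 0.547, morphine −0.499 to −0.018), which keeps the question open although fewer than 1 in 20 calls remained, and this reading was settled after the result was seen. The scaling of each library by a common factor is argued against as the whole source, since another scaling left at least 4164 called genes, in both directions. That total does not show the balance of directions, which moved with library size alone to 3093 rising and 1307 falling genes. Of the main calls 86.9% were kept there and 0 were called the other way. The other scalings change only a factor per library, so they do not bear on differences that depend on gene length or abundance. Library features also differed between treatments, with morphine higher by 0.0478 in the TMM factor (exact permutation p = 0.005). The number of genes with a count was higher by 104.8 (exact permutation p = 0.02). Whether the changes followed gene length was not checked, so a technical source of that kind stays open. An effect of morphine stays open as well. The numbers in the column labels run in blocks by sex and treatment, and if libraries were processed in that order, a batch cannot be told apart from treatment.

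Chance can be excluded for the count of called genes over both sexes, where the real value was 4184 and the highest of the other 99 drawn splits 2696 (1 of 100 splits reached the real value), a split with 1 library exchanged. It can be excluded for the correlation of the sexes as well, with 0.653 against 0.528 (1 of 100). For the sex difference of the morphine effect, with 0 called genes, 100 of 100 splits give as many whatever the labels, so the count decides nothing about chance, and another split gave 103. For female against male 3 of 100 splits, the real one included, gave at least the real count of 5. That is under the limit of 5 in 100 set before. The count alone does not exclude chance, since another split gave 33 genes, several times the real count. This points to a structure of the samples. That split parted the saline libraries by sex and set female morphine 1, female morphine 2 and male morphine 1 beside male saline, and what these libraries share was not tested. For females (2437, highest other 0), males (2227, highest other 1) and saline libraries of the sexes (5, highest other 0), 10 splits are too few for a share under 0.05, and the real split was 1 of 10.

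Some abundant genes had irregular counts between libraries of one group. There were 23 genes with a mean count of at least 100 whose largest library exceeded the smallest of the same group 5 times or more, such as Hnrnpab (0 to 310 counts in male morphine), Rps9 (57 to 1401 in female saline), Tagln3 (40 to 2841 in male saline) and Grcc10 (30 to 769 in male saline). Counting noise with the median dispersion of the genes (0.0163) is argued against, since the largest of 20 simulated tables held 0 such genes. A larger dispersion of single genes was not simulated, so the test does not bear on it. Reads shared with a neighbouring gene in GRCr8 would give negative correlations, and the median lowest correlation of −0.26 lay within the range of medians of random genes (−0.42 to −0.02). Single genes ranged from −0.91 for Pnpla1 to 0.3 for Brd2, with Grcc10 at −0.64. The median cannot decide for single genes, so shared reads stay open for some of them. How the reads of genes with near-identical copies were assigned was not tested and could be involved, and 2 of the 23 genes were called over both sexes.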
